A study of Mus musculus with 6 samples.

How the data were processed

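RNA was sequenced from hand-picked pancreatic islets of C57BL/6 mice aged 20 weeks that had eaten a 60% high fat diet for 8 weeks. Per the labels, 3 libraries came from control mice (β-Slc4a4+/+) and 3 from mice lacking Slc4a4 selectively in beta cells, each made from total RNA with a kit that does not mark strand. The submitters' processing notes list TopHat2 2.0.6, StringTie 2.1.3, R 3.6.1, edgeR 3.1.1 and the mouse build mm10, without saying which step each one served, and the counting rule and filters are not given in the sources used here.

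The authors deposited 1 table of CPM values with 24420 gene rows and 6 library columns, normalized to library size as the values show. Each column summed to between 999899 and 999929, and the submitters' processing notes do not describe the scaling. All 146520 values were whole multiples of the smallest value in their column, within a tolerance of 1e-04 of 1 step, so counts were recovered as those multiples, from 111344485 to 150364448 per library. The recovered counts were not single reads. Low values piled up at 3, 6, 9, 11, 14, 17, 19 and 22 steps, a spacing of 8 steps for 3 peaks. The largest pile, 858 values, lay at 1 step, outside that spacing. The spacing is as estimates from base coverage would give, and it puts the depth at 41.8 to 56.4 M fragments per library if each peak is 1 fragment. That origin was not tested further, so this depth and the floor below are approximate. A floor for genes at 0 was set at 3 fragments per library, and floors cover counting error only. The table held 7596 rows at 0 in all libraries. In 27 rows a spreadsheet had turned the gene name into a number, and these rows stayed in the tests but are not named.

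Genes were kept at 1 CPM or more in at least 3 of the 6 libraries, which left 12747. The values log2(CPM + 1), with a pseudocount of 1 and no further scaling, were compared between groups in limma 3.58.1 (R 4.3.3), with an empirical Bayes variance trend and robust fitting. Adjusted p is Benjamini-Hochberg throughout, a gene or list was called below 0.05, and "rose" or "fell" is used for calls of this kind. Log2 changes are knockout minus control on the log2(CPM + 1) scale, which understates the change of genes with low values, and their errors are standard errors. All 6 libraries entered the main fit, with no replicate block. Alternatives that left out a library or added a block are named as such. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. No replicate pair agreed within sampling noise: chi-square per degree of freedom on the fragments ran from 14.4 to 58.2. No library date or batch is given.

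Of 39 gene lists written before the data were examined, 35 were tested with limma's camera at an inter-gene correlation of 0.01, with an estimated correlation and limma's fry beside it, and p-values were adjusted over the 35. A list needed at least 5 measured members. Where no test is named, a list said to be called or not called was judged by camera at the correlation of 0.01 on all 6 libraries. Camera used the variance trend of the gene fit. That setting was fixed after its default, a flat variance prior, had been seen to call 2 lists in place of 5. Not tested were lymphocyte markers (1 measured), adipocyte markers (2 measured), mitochondrially encoded genes (0 rows in the table) and sex-linked genes, which were a check alone and were male-like in all 6 libraries, with Ddx3y at 51.1 to 69.5 CPM and Xist at no more than 0.187 CPM.

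Transcript GC content, length and coordinates came from GENCODE M21, an annotation of mm10, to which 24018 of the 24420 rows matched by symbol, 669 of them through an older symbol. After the values had been examined, a GC correction was added: in each library, a natural spline with 5 degrees of freedom of the deviation from the gene mean on GC content was subtracted before the limma fit. Of the tested genes, 99.3% had a GC value. A GC-corrected result is given for each named gene whose call or direction it changes and for each list whose call it changes, except where the check is void for lack of GC values. Counts of members after correction are given for some lists only.

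The scripts were tested on simulated counts with 200 changed genes. Without a GC trend, limma called 41.8% of the 1.5-fold, 74.2% of the 2-fold and 98.5% of the 4-fold changes among 12600 tested genes, with 12 unchanged genes called. With the observed GC trend added, 497 unchanged genes were called without the correction and 19 with it, among 12596 tested genes. The GC-corrected list test then also called 1 of the 34 lists that had not been shifted. The added trend was the spline fitted to these libraries, so a correction of the same form was bound to remove it. These counts check the scripts alone. They do not measure how many calls in the real data come from the trend.

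Genes are named by a rule fixed before the data were examined. It takes Slc4a4, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, leaving out predicted genes and pseudogenes, the 4 members with the smallest p of each called list and 2 of each other list. It always takes the islet hormones Ins1, Ins2, Gcg, Sst and Ppy, the beta cell genes Ucn3, Slc2a2, Mafa, Pdx1, Nkx6-1 and Aldh1a3, and the Slc4 family. Some genes that the rule takes are not reported here. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and 5 CPM), median-of-ratios, TMM and quantile scaling, a limma fit without trend and robust options, array weights, a minimum change of 1.5-fold, treat at 1.2-fold, a replicate block and each library left out. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered counts, and edgeR called 3086 genes, 2840 of them called in the same direction by limma. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.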

Results

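The series measured gene expression in pancreatic islets, the hormone-secreting cell clusters of the pancreas, after 8 weeks of a 60% high fat diet. It compared 3 libraries from control mice with 3 from mice in which Slc4a4 had been removed from the insulin-producing beta cells. Slc4a4 encodes NBCe1, a transporter that carries sodium and bicarbonate into or out of the cell together with net charge. The comparison asks which islet transcripts differ when beta cells lack this transporter during diet-induced metabolic stress. Ins1 and Ins2 together took 28.0% to 32.9% of each library.

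Slc4a4 (chromosome 5, 88886818 to 89239653, mm10) was at 7.09 ± 2.26 CPM in control libraries and 3.40 ± 1.65 CPM in knockout libraries (SD, n = 3 each). The control libraries held 8.30, 8.49 and 4.48 CPM and the knockout libraries 1.61, 3.75 and 4.84 CPM, so the library labelled control 3 lay inside the knockout range. The two-sided exact permutation p of the difference in means was 0.2, and since 3 against 3 libraries allow no p below 0.1, this test could not reach 0.05. The limma change of -0.91 ± 0.32 on the log2 scale missed the threshold (adjusted p = 0.0697). It passed in 6 of the alternative settings, among them DESeq2 (adjusted p = 0.0156) and the fits without control 3 (0.0131) or without knockout 3 (0.0371), and over all alternatives the adjusted p ran from 0.0131 to 0.326. The labels do not say which exon was removed, and transcripts of the other islet cells are counted too, so the total is a weak check of the genotype.

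In the knockout islets 1655 genes rose and 1391 fell, out of 12747 tested (limma, Benjamini-Hochberg). The groups did not overlap for 2975 of these 3046 genes, and they did not overlap for 40.3% of all tested genes, where chance gives 10%. Changes were mostly small, with 140 called genes at 2-fold or more on the log2(CPM + 1) scale. The direction followed transcript GC content. In the quintile of genes with the lowest GC content 17 rose and 661 fell, and in the quintile with the highest 1098 rose and 19 fell. Across genes, which are not independent replicates, Spearman's correlation of fold change with GC content was 0.629. After GC correction, a step added once this had been seen, 779 genes rose and 1121 fell, and 515 rises and 759 falls were called both ways. The slope of the log2 values on GC content was -0.18, -0.28 and -0.02 per 10 percentage points in control libraries 1, 2 and 3, and 0.11, 0.16 and 0.21 in the knockout libraries, so control 3 stood apart from the other controls. Without control 3, 4514 genes were called, and without any other library the count lay between 1457 and 2198. The share of rises was 54.3%, 65.9% without control 1 and 45.8% without control 3.

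**Figure D1:**
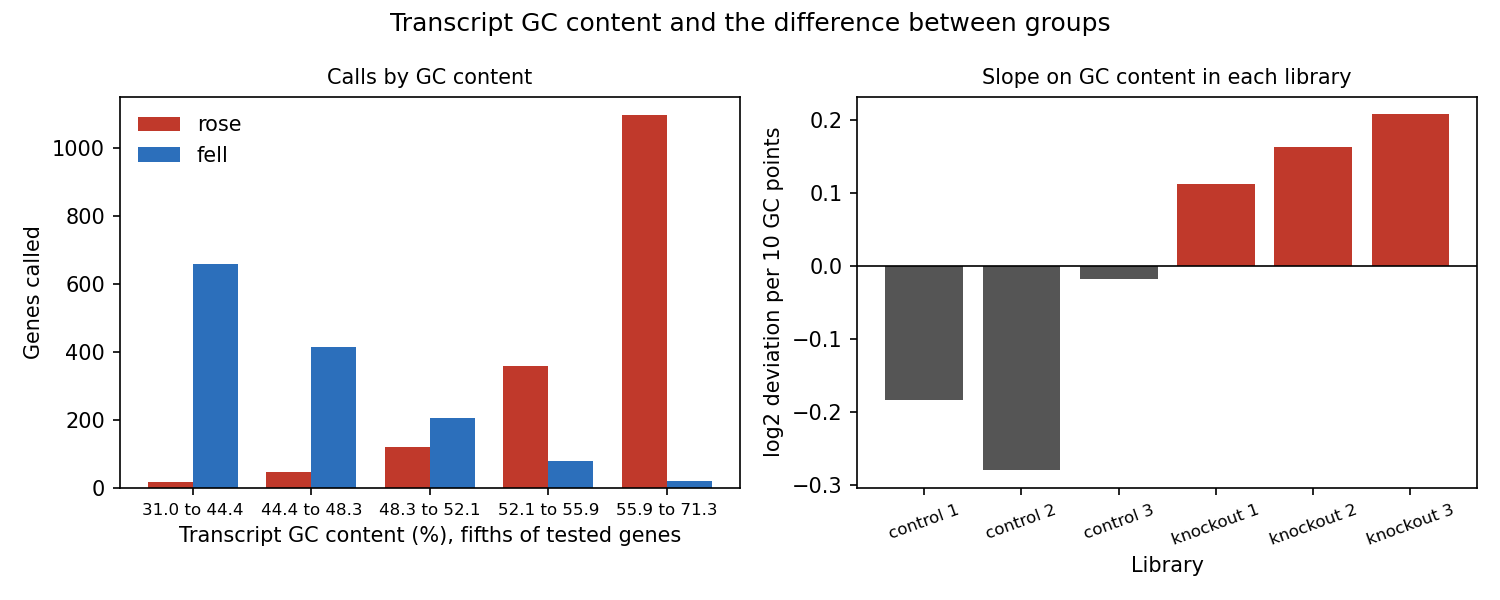
Left, the number of genes that rose (red) or fell (blue) in knockout islets in each quintile of tested genes by transcript GC content (%). Right, the slope of each library's log2 deviation from the gene mean on GC content, per 10 percentage points. Falls outnumber rises 661 to 17 in the lowest quintile and rises outnumber falls 1098 to 19 in the highest, and the 3 control slopes (grey) lie below the 3 knockout slopes (red).

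Most of the measured cell cycle genes fell in the knockout islets. Top2a, the DNA topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), fell from 17.9 ± 1.60 to 0.460 ± 0.509 CPM, and Mki67, the proliferation marker Ki-67 (chromosome 7, 135689784 to 135716361), from 16.1 ± 1.72 to 1.23 ± 0.495 CPM (SD, n = 3). Of 32 measured cell cycle genes, 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median log2 change of -0.79. The kinase Cdk1 fell by 2.07 ± 0.23 and its mitotic partner Ccnb1 fell by 1.96 ± 0.23 on the log2 scale. Camera called the list (adjusted p = 1.4e-12), also with an estimated correlation (adjusted p = 0.0447) and after GC correction, where the median was -0.67 and 18 members fell. The largest falls of the whole comparison held further genes of mitosis and proliferation, namely the kinetochore protein Cenpf, the spindle proteins Hmmr and Tpx2, the mitotic kinases Nek2 and Pbk, and the microtubule regulator Stmn1. Their log2 changes ran from -2.79 in Cenpf to -2.09 in Tpx2, with every knockout library below every control library. Cenpf, at 0 in 2 knockout libraries, missed the threshold in edgeR and in DESeq2, with adjusted p = 0.105 and 0.0998. Of 14 measured genes of senescence and cell cycle arrest, 1 rose and 3 fell (1 and 4 adjusted over the list alone). Gadd45b, a stress-inducible growth arrest gene, rose by 1.09 ± 0.16 and the growth factor receptor gene Igf1r fell by 0.64 ± 0.08 on the log2 scale, and the list as a whole was not called (adjusted p = 0.712).

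**Figure D2:**
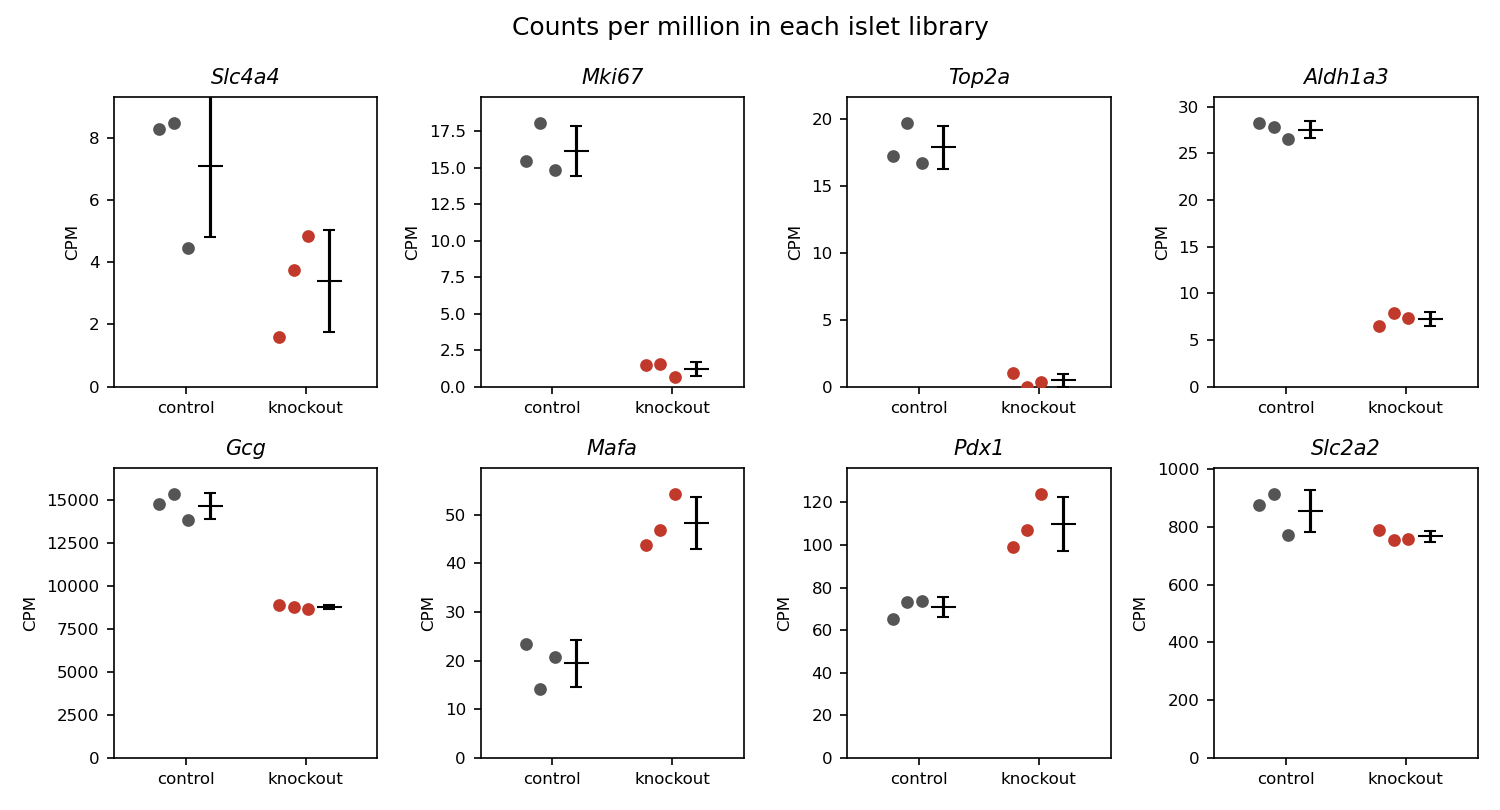
CPM of 8 genes in each library, 1 point per library, with the group mean and SD (n = 3) drawn beside the points; control libraries are grey and knockout libraries red, and each axis starts at 0. Mki67, Top2a, Aldh1a3 and Gcg lie lower in all 3 knockout libraries and Mafa and Pdx1 higher, while the groups overlap for Slc4a4 and Slc2a2.

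Outside the cell cycle, large changes were found in a neuropeptide, a protease, the transcript D17H6S56E-5 and a pair of neighbouring genes. Vip, which encodes vasoactive intestinal peptide (chromosome 10, 5639218 to 5647617), fell from 5.34 ± 0.546 to 0.0505 ± 0.0535 CPM (SD, n = 3; adjusted p = 4.57e-06). Capn11, a calpain protease gene (chromosome 17, 45630204 to 45659325), was at 3.508 ± 1.002 CPM in controls and at 0 in all 3 knockout libraries, at least 57.6-fold lower against a floor of 3 fragments per library. D17H6S56E-5 fell from 16.5 to 1.78 CPM. Rab39, a small GTPase of vesicle traffic (chromosome 9, 53684110 to 53706232), rose from 3.88 ± 0.813 to 28.2 ± 1.56 CPM (adjusted p = 2.33e-07). Slc35f2, a solute carrier gene beside it (53771538 to 53818154), rose from 0.0909 ± 0.157 to 6.34 ± 0.976 CPM. Further large rises, each called before and after GC correction, were Fam53b (log2 change 1.78 ± 0.19), Yaf2 (1.64 ± 0.15), the protocadherin Pcdhga3 (1.42 ± 0.20), the histone gene Hist2h2aa1 (1.35 ± 0.16, and 0.81 after GC correction), the homeobox gene Barhl1 (1.34 ± 0.20) and the GABA receptor subunit gene Gabra4 (1.34 ± 0.22). Lppr2, Zbed3 and Pcsk1n rose by 1.88, 1.71 and 1.67, and these 3 calls ended when 1 of several libraries was left out. Members of the protocadherin, histone and globin families share sequence, so their values are uncertain.

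Among beta cell genes the insulin transcripts were not called, while the transcription factor genes Mafa and Pdx1 rose and Aldh1a3 fell. Aldh1a3, an aldehyde dehydrogenase that marks failing beta cells (chromosome 7, 66390890 to 66427517), fell from 27.5 ± 0.920 to 7.25 ± 0.723 CPM (SD, n = 3; adjusted p = 9.07e-07). Mafa, a transcription factor of mature beta cells (chromosome 15, 75745490 to 75748228), rose from 19.4 ± 4.75 to 48.3 ± 5.37 CPM, and Pdx1 rose from 70.9 ± 4.76 to 110 ± 12.7 CPM. GC correction left both called but smaller, from 1.29 ± 0.16 to 0.72 ± 0.11 for Mafa and from 0.62 ± 0.09 to 0.42 ± 0.07 for Pdx1 on the log2 scale. Ins1 and Ins2 were at log2 changes of 0.10 ± 0.05 (adjusted p = 0.128) and 0.12 ± 0.06 (adjusted p = 0.157), and both were called as higher without control 3 (adjusted p = 6.5e-06 and 1.7e-07). Ucn3, a peptide of mature beta cells, and the glucose transporter gene Slc2a2 were not called, at -0.05 ± 0.05 and -0.15 ± 0.06, and after GC correction Slc2a2 was at 0.08 ± 0.03 (adjusted p = 0.0678). Several settings did call Slc2a2, as lower in DESeq2 (adjusted p = 0.0179) and as higher with a correction for GC content and length (0.0303). Nkx6-1 rose by 0.29 ± 0.07 and Iapp, the amyloid peptide secreted with insulin, fell by 0.27 ± 0.04, and GC correction ended both calls at -0.06 ± 0.05 and -0.03 ± 0.07. Of 22 measured beta cell identity genes 6 rose and 4 fell (7 and 5 adjusted over the list alone). Camera did not call the list (adjusted p = 0.343), while fry called it as higher (adjusted p = 0.0483). After GC correction 7 rose and 1 fell, and the list was called as higher (adjusted p = 0.0325, and 0.246 with an estimated correlation). Leaving out one library ended this call (adjusted p up to 0.133).

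The other beta cell lists were not called by the main camera test as uncorrected values, while fry called the dedifferentiation and progenitor list as lower (adjusted p = 0.0116). Of 8 measured dedifferentiation and progenitor genes, Aldh1a3 alone was called before GC correction and 2 fell after it, Aldh1a3 and Cd81, the latter named once its values had been seen. Myc was at 0.60 ± 0.25 (adjusted p = 0.101), and the list's adjusted p was 0.893, its median (0.07) and mean (-0.09) differing in sign. Among 11 beta cell disallowed genes, Fcgrt rose and 0 fell, Fcgrt's call ended after GC correction, Arap2 was at -0.62 ± 0.24 (adjusted p = 0.0774), and the list's adjusted p was 0.966. Counts for both lists were the same adjusted over the list alone. Of 25 insulin granule and exocytosis genes 4 rose and 9 fell, the same adjusted over the list alone (list adjusted p = 0.343). Pclo, a scaffold of secretory sites, fell by 0.77 ± 0.11, and the granule protein gene Chga rose by 0.33 ± 0.05 before GC correction and was at 0.00 ± 0.01 after it. Of 26 ion channel and calcium genes 5 rose and 5 fell, the same adjusted over the list alone (list adjusted p = 0.928). The calcium channel subunit genes Cacna2d1 and Cacna1c fell by 0.56 ± 0.09 and 0.48 ± 0.08 on the log2 scale, and by 0.31 ± 0.05 and 0.46 ± 0.06 after GC correction. With that correction 0 members of this list rose and 8 fell, and the list was called as lower (adjusted p = 0.00494, and 0.271 with an estimated correlation). It was not called as lower when transcript length was added to the correction.

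The alpha cell hormone transcript fell and that of delta cells rose. Gcg, the glucagon gene of alpha cells (chromosome 2, 62474530 to 62483650), fell from 14662 ± 760 to 8789 ± 133 CPM (SD, n = 3; adjusted p = 2.33e-07). Of 13 measured alpha cell markers 5 fell and 0 rose, the same adjusted over the list alone, with Tmem27, Ttr and Slc7a2 at log2 changes of -0.51, -0.31 and -0.29 (-0.26, -0.19 and -0.12 after GC correction). Tmem27 and Slc7a2 are also expressed by beta cells, and Ttr lost its call after GC correction. The GC-corrected limma call of Slc7a2 ended when 1 library was left out (adjusted p up to 0.0937). The transcription factor genes of alpha cells were not among the called members. The list was called as lower (adjusted p = 0.038, and 0.00498 after GC correction), but not with an estimated correlation (adjusted p = 0.432), with array weights or with camera's flat variance prior. Sst, the somatostatin gene of delta cells, rose from 680 ± 60.0 to 1101 ± 126 CPM (adjusted p = 0.00103, and 0.0424 after GC correction), while Arg1 fell and lost its call after GC correction. Of 9 delta cell markers 1 rose and 1 fell, the same adjusted over the list alone (list adjusted p = 0.928). Of 6 PP and epsilon cell markers 1 rose and 3 fell (1 and 4 adjusted over the list alone), Pyy rising by 0.59 ± 0.09 (0.31 after GC correction) and Spp1, which duct cells express too, falling from 34.9 to 18.8 CPM. Ppy, the pancreatic polypeptide gene, was at -0.25 ± 0.09 (adjusted p = 0.0835) and was called as lower after GC correction at -0.51 ± 0.08 (adjusted p = 0.0256). The GC-corrected limma calls of Sst, Pyy and Ppy each ended when 1 library was left out (adjusted p up to 0.143, 0.0973 and 0.0963). In the main camera test the PP and epsilon list was called with the correction and not without it (adjusted p = 0.107 before, 0.0325 after and 0.254 after with an estimated correlation). Leaving out one library ended that call (adjusted p up to 0.142). Fry called the list as lower without the correction (adjusted p = 0.000502).

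Several genes of fatty acid use fell, and several of glucose use rose before GC correction. Of 22 genes of fatty acid oxidation and PPAR targets 1 rose and 7 fell (2 and 10 adjusted over the list alone). Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell from 15.5 ± 0.654 to 6.02 ± 1.05 CPM (SD, n = 3). Cpt1a, which admits fatty acids to mitochondria, fell from 103 ± 5.45 to 67.7 ± 1.53 CPM. The lipid droplet gene Plin2 fell from 28.7 ± 2.80 to 19.4 ± 1.54 CPM. The nuclear receptor gene Ppard rose by 0.55 ± 0.10 and lost its call after GC correction. The list was called as lower (adjusted p = 0.038, and 0.00494 after GC correction), but not with an estimated correlation (adjusted p = 0.432). Of 18 glycolysis genes 6 rose and 0 fell, the same adjusted over the list alone, among them the phosphofructokinase gene Pfkl by 0.54 ± 0.09. This list (adjusted p = 0.038, and 0.432 with an estimated correlation) had an adjusted p of 0.974 after GC correction, with 2 members rising and 2 falling. The glycolysis call also ended without knockout 1 (adjusted p = 0.0555), with array weights, in edgeR and with camera's flat variance prior (adjusted p = 0.0825). Pfkl stayed called at 0.27 ± 0.07, Gapdh went from 0.20 ± 0.06 to -0.05 ± 0.04, and Pkm turned from a rise of 0.19 ± 0.05 to a fall of -0.11 ± 0.03.

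Of 75 nuclear genes of oxidative phosphorylation 20 rose and 2 fell (22 and 5 adjusted over the list alone), and 12 rose and 5 fell after GC correction. Ndufs7 and Atp5d rose by 0.76 ± 0.12 and 0.53 ± 0.10 on the log2 scale, followed by Ndufs8 and Ndufb10 at 0.51 and 0.47. After GC correction Ndufs7, Ndufs8 and Ndufb10 were at 0.38, 0.35 and 0.28, and Atp5d lost its call. The GC-corrected limma calls of Ndufs8 and Ndufb10 ended when 1 library was left out (adjusted p up to 0.0631 and 0.141). The list was called as higher (adjusted p = 0.0408), but not with an estimated correlation (adjusted p = 0.432), after GC correction (adjusted p = 0.102), with camera's flat variance prior, with median-of-ratios or TMM scaling, or without control 1, knockout 1 or knockout 2 (up to 0.208). Of 29 TCA cycle genes 2 rose and 7 fell, the same adjusted over the list alone (list adjusted p = 0.231), and the pyruvate carboxylase gene Pcx, up by 0.32 ± 0.07, was at 0.02 ± 0.05 after GC correction. Of 26 genes of mitochondrial dynamics and biogenesis 3 rose and 2 fell (2 and 2 adjusted over the list alone), led by Esrra at 0.62 and Opa1 at -0.28, both calls ending after GC correction (list adjusted p = 0.966). Of 26 genes of lipid and cholesterol synthesis 2 rose and 4 fell, the same adjusted over the list alone (list adjusted p = 0.744). The lipogenic regulator Srebf1 rose from 98.8 to 163 CPM (log2 change 0.72, and 0.40 after GC correction), and Srebf2 rose by 0.39 ± 0.07 before it only.

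**Figure D3:**
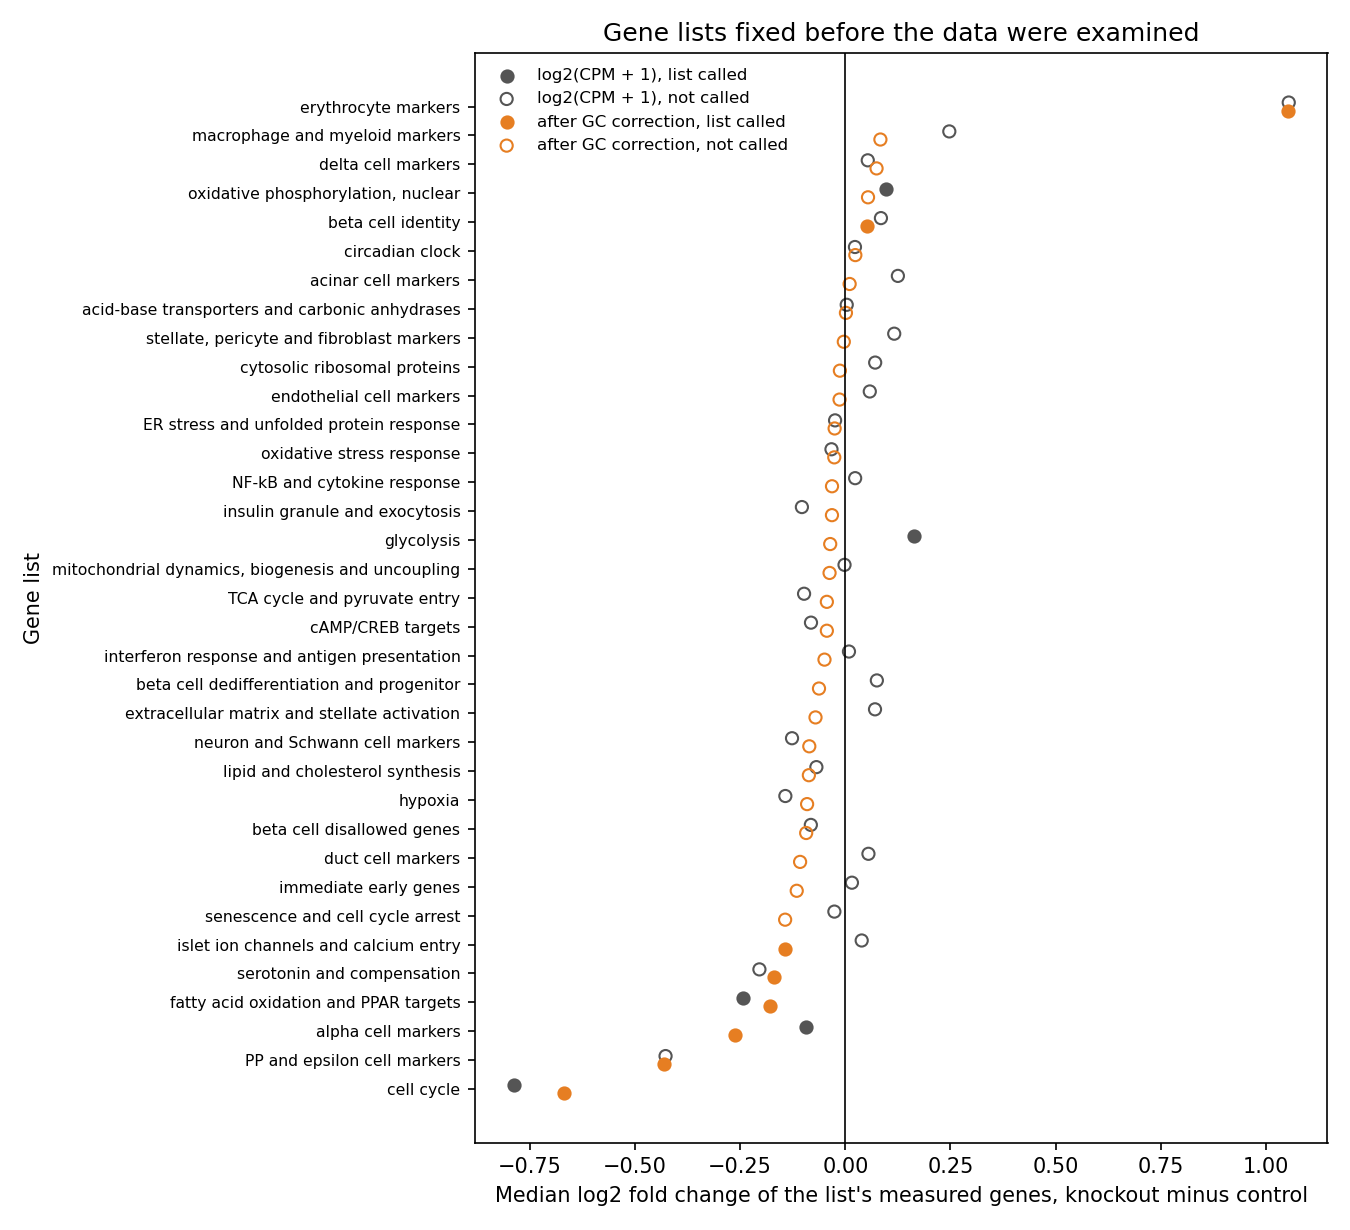
Median log2 fold change, knockout minus control, over the measured genes of each of the 35 lists, as log2(CPM + 1) values (grey) and after GC correction (orange); filled points are lists called by camera and open points lists that were not. Cell cycle lies lowest at -0.79 and -0.67, and glycolysis moves from 0.16 to -0.04.

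Other members of the Slc4 bicarbonate transporter family differed little or in both directions before GC correction. After it Slc4a3 alone was called, as higher. The anion exchanger gene Slc4a3 rose from 35.5 ± 3.25 to 58.4 ± 1.91 CPM (SD, n = 3; adjusted p = 0.000192, and 7.41e-05 after GC correction). Slc4a2 rose by 0.45 ± 0.10 and Slc4a10 fell by 0.33 ± 0.10 on the log2 scale, and both calls ended after GC correction. Slc4a7 and Slc4a8 were at -0.22 ± 0.09 (adjusted p = 0.104) and 0.00 ± 0.10. After GC correction they were at 0.009 ± 0.04 (adjusted p = 0.923) and 0.008 ± 0.09 (adjusted p = 0.967). Slc4a7 was called as lower without control 3 (adjusted p = 4.5e-05) and in 6 other settings without GC correction. Slc4a9 and Slc4a11 were at 0 in all libraries, and Slc4a1 and Slc4a5 averaged under 0.03 CPM in both groups. Of 20 measured acid-base transporters and carbonic anhydrases 3 rose and 3 fell (3 and 4 adjusted over the list alone) (list adjusted p = 0.966).

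Stress and signalling lists held strong single changes, and none was called by the main camera test in the uncorrected values. There fry called the oxidative stress list (adjusted p = 0.0234) and the serotonin and compensation list as lower. Camera's adjusted p without one library went as low as 0.0189 for ribosomal protein genes. The antioxidant gene Gpx3 fell from 316 ± 4.94 to 183 ± 7.01 CPM, and Sesn2 rose before GC correction only (oxidative stress: 4 rose and 3 fell, 4 and 5 adjusted over the list alone, of 23; list adjusted p = 0.738). Fosb, an immediate early gene, fell from 25.0 ± 3.06 to 6.40 ± 0.975 CPM, while Npas4, induced by calcium entry, rose from 3.40 ± 1.22 to 7.92 ± 0.698 CPM (SD, n = 3). Of 20 immediate early genes 4 rose and 4 fell, 5 and 4 adjusted over the list alone (list adjusted p = 0.928). Of 16 CREB targets 4 rose and 2 fell, the same adjusted over the list alone, with the phosphodiesterase gene Pde10a falling by 1.02 ± 0.12 on the log2 scale (list adjusted p = 0.966). Of 31 genes of ER stress 7 rose and 7 fell (8 and 8 adjusted over the list alone), Chac1 rising from 11.9 to 23.6 CPM and Asns falling from 167 to 120 CPM (list adjusted p = 0.928). Of 12 genes of cytokine response 1 rose and 2 fell, the same adjusted over the list alone, Il1r1 falling from 809 to 488 CPM and Socs3 by 0.56 ± 0.11 (0.90 after GC correction) (list adjusted p = 0.928). Among 27 interferon and antigen presentation genes Tap2 rose and B2m fell (1 and 0 adjusted over the list alone), both before GC correction only (list adjusted p = 0.928). Of 14 hypoxia genes 0 rose and 3 fell (2 adjusted over the list alone), P4ha1 and Ero1l among them at -0.44 and -0.53 (-0.31 and -0.30 after GC correction) (list adjusted p = 0.105). Of 18 clock genes 6 rose and 2 fell, the same adjusted over the list alone, and 2 rose and 3 fell after GC correction, with Per2 rising by 0.60 ± 0.08 and Per1 by 0.47 ± 0.09, the latter before GC correction only (list adjusted p = 0.516). Of 57 ribosomal protein genes 17 rose and 6 fell, 18 and 7 adjusted over the list alone (list adjusted p = 0.343), and 3 rose and 14 fell after GC correction. Rpl18 was at 0.42 and Rpl5 at -0.37, and at 0.36 and -0.16 after the correction. Both GC-corrected limma calls ended when 1 library was left out (adjusted p up to 0.153 and 0.134). Of 7 genes of serotonin synthesis and beta cell compensation 1 rose and 4 fell, the same adjusted over the list alone. The prolactin receptor gene Prlr fell from 510 to 315 CPM (log2 change -0.68, and -0.42 after GC correction). Gc fell from 174 to 113 CPM, and which islet cells held its transcripts was not tested. In the main camera test the serotonin and compensation list was called with GC correction and not without it (adjusted p = 0.0910 before, 0.00498 after and 0.246 after with an estimated correlation). Without the correction fry called the list as lower (adjusted p = 0.0116), and camera's adjusted p without one library went as low as 0.0466.

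Markers of the non-endocrine cells of an islet preparation were not called as lists by the main camera test in the uncorrected values. There fry called macrophage and erythrocyte markers as higher (adjusted p = 0.00991 and 0.00543). Camera's adjusted p without one library went as low as 0.00439 for erythrocyte markers. Of 15 endothelial markers 4 rose and 0 fell, among them Plvap, from 77.9 to 132 CPM (log2 change 0.75, and 0.33 after GC correction), and Eng, by 0.70 ± 0.12 (0.42 after it) (list adjusted p = 0.505). Of 14 stellate and fibroblast markers 0 rose and 2 fell, Dcn from 1.89 to 0.166 CPM and Col3a1 from 11.3 to 5.47 CPM (list adjusted p = 0.966). Of 19 extracellular matrix genes 3 rose and 4 fell, Timp3 by 0.34 ± 0.07 (list adjusted p = 0.906). Of 22 macrophage markers 4 rose and 0 fell, with H2-Eb1 at 0.43 and H2-Ab1 at 0.42, the latter before GC correction only (list adjusted p = 0.153). Of 5 neuron and Schwann cell markers Mbp fell by 0.23 ± 0.07, and the list's adjusted p was 0.738. Of 16 acinar markers 1 rose and 2 fell, the trypsinogen paralogs Try4 and Try5, near-identical copies whose values are uncertain, at 3.02 and 3.01 CPM in controls (list adjusted p = 0.928). Of 11 duct markers 1 rose and 2 fell, Spp1 and Tspan8, the latter before GC correction only (list adjusted p = 0.906). Counts for these 7 lists were the same adjusted over the list alone. Of 6 erythrocyte markers 2 rose, Hbb-bt and Hbb-b2, also adjusted over the list alone (list adjusted p = 0.0592), and the GC check is void for this list because only 4 of the 6 have a GC value. Among the lists that were not called, the median and the mean differed in sign for dedifferentiation, disallowed, extracellular matrix, duct, acinar, stellate, cytokine, interferon, immediate early, ER stress, CREB and mitochondrial dynamics genes. For CREB targets camera pointed up against a median of -0.08, for acinar markers up against a mean of -0.01, and for stellate markers up against a mean of -0.01.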

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

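Chosen after the data were examined were the GC corrections, alone and with length, a replicate block, a left-out library or an estimated correlation, and camera's variance trend, which is behind the 5 list calls and was set after its default flat prior had been seen; the rest were planned. The cell cycle list was called as lower in every setting run, with an adjusted p of at most 0.0447. The gene count of 3046 stayed within 1.5 times under both pseudocounts, both filters, 3 scalings, edgeR, DESeq2 and the replicate block (3464). It was 1718 without trend and robust fitting, 5149 with array weights, 780 with a 1.5-fold minimum and 285 with treat, where the stricter rule itself lowers it. It was 1900 with GC correction, 1805 with GC and length correction, 1942 with GC correction and a replicate block, 1457 to 4514 without one library, and 1147 to 2061 with GC correction and without one library. The share of rises was 54.3% and ran from 49.6% to 51.2% under the 3 scalings, but was 41.0% with GC correction, 64.0% without trend and robust fitting, 47.7% with array weights and 45.8% to 65.9% without one library. Slc4a4 kept its sign in every setting that tested it and passed at -0.97 with quantile normalization, -1.01 with array weights and -1.05 in DESeq2. It ran from -1.17 to -0.57 without one library and from -1.03 to -0.43 with GC correction as well, and the 5 CPM filter removed it. Of 35 lists, 5 were called, against 3 with array weights, 1 with an estimated correlation, 12 with fry, 2 with a flat variance prior, 8 with GC correction with or without a replicate block (erythrocyte markers, for which that check is void, among the 8), 1 with GC correction and an estimated correlation, 3 to 6 without one library and 6 to 10 with GC correction and without one library. The list call did not apply to DESeq2 or to fold minimums.

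Reversals came with GC correction, where the removed trend itself moves these GC-rich or GC-poor genes; sign changes between uncalled values are not counted. With GC correction, with length added and with a replicate block, the log2 changes were -0.11, -0.11 and -0.11 in Pkm, -0.0467, -0.0623 and -0.0467 in Gapdh and -0.0597, -0.0692 and -0.0597 in Nkx6-1. With length added, Chga was at -0.00669, Slc2a2 at 0.0902, and glycolysis at an adjusted p of 0.802. Ion channels were called as lower with GC correction (adjusted p = 0.00494) and with a replicate block (0.00582). With GC correction and without one library, the ranges were -0.127 to -0.0912 in Pkm, -0.0853 to -0.0173 in Gapdh, -0.0868 to -0.0297 in Nkx6-1, -0.00705 to 0.0154 in Chga, 0.0527 to 0.0802 in Slc2a2, -0.00947 to 0.0570 in Pcx, -0.0761 to 0.0385 in Iapp and -0.0375 to 0.0117 in B2m, and the adjusted p was 0.00104 to 0.0224 for ion channels and 0.809 to 0.976 for glycolysis. Without that correction and without one library, none of these turned: the values furthest from the corrected ones were 0.235 in Pkm, 0.244 in Gapdh, 0.345 in Nkx6-1, 0.367 in Chga, -0.222 in Slc2a2, 0.390 in Pcx, -0.293 in Iapp and -0.304 in B2m, with an adjusted p of up to 0.997 for ion channels and 0.0319 to 0.0555 for glycolysis. For the other changes the cause was not tested. Of 107 named genes other than Slc4a4, 83 kept side and sign with GC correction, 20 lost their call and 1 gained one. The values gave no clear sign that the replicate numbers pair the libraries, and they cannot exclude a shared litter or day. Same-numbered deviations correlated at -0.02, 0.00 and 0.06, against at most 0.02, 0.08 and 0.00 between each control and the other-numbered knockouts. Under the block 1 named gene lost its call and 4 gained one. In data simulated from the means and library sizes of these libraries 41.8% of 1.5-fold changes were recovered, and whether depth or spread limited this was not tested.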

Other observations

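All gene groups in this part and all tests of explanations were chosen after the values had been seen, except the cell type and cell cycle lists. Genes of the amino acid response, many of them targets of the transcription factor ATF4, changed in both directions: of 36 measured, 5 rose and 11 fell, with a median of -0.15 on the log2 scale, and after GC correction 3 rose and 17 fell, with a median of -0.22. Since this group and those below were drawn up from the values, no list test is given for them. The serine synthesis gene Psat1 fell from 23.1 ± 2.55 to 11.8 ± 1.41 CPM (SD, n = 3), Nupr1 from 80.7 to 48.4 CPM and the mitochondrial folate enzyme genes Aldh1l2 and Mthfd2 from 105 to 67.4 and from 83.8 to 59.5 CPM. Chac1 and Ddit3, which stand downstream of ATF4 too, rose, and Atf4 itself, Trib3 and Sesn2 rose before GC correction only. Among 24 chaperones 2 rose and 9 fell (4 and 8 after GC correction), Hsp90aa1 from 485 to 321 CPM and the mitochondrial Hspd1 and Hspe1 among the falls, while the near-identical copies Hspa1a and Hspa1b rose.

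Of 36 splicing factors and nuclear RNAs 13 rose and 1 fell, with a median of 0.15, and after GC correction 24 rose and 1 fell, with a median of 0.33. The noncoding RNA Meg3 rose from 835 to 1242 CPM and the splicing genes Snrnp70 and Leng8 from 165 to 286 and from 131 to 234 CPM, whereas the nuclear RNA Malat1 fell from 822 to 563 CPM. Of 16 measured histone genes 7 rose and 0 fell (4 and 0 after GC correction). Of 39 clustered protocadherins 5 rose and 3 fell. Long transcripts were lower: the GC-corrected median was -0.13 over 701 genes of 8 to 16 kb and -0.34 over 27 genes of 16 kb or more, and it was 0.02 over 657 genes under 1 kb, with no test of these classes. Control 3 stood apart here too, deviating by 0.0804 at 16 kb or more, against 0.207 and 0.227 in the other controls.

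Fold change rose with transcript GC content, by 0.321 ± 0.00415 log2 units per 10 percentage points over all genes. Errors here are standard errors across genes, which share the same 6 libraries and are not independent. They leave out the spread of the slopes between libraries and so understate the uncertainty. Markers of endothelial, stellate, macrophage, lymphocyte and nerve cells, which were not targeted by the knockout, had a slope of 0.363 ± 0.0849 over 57 genes, which argues against a response of beta cells alone. Transcript length is also disfavoured as the whole cause, since the partial rank correlation with GC given length was 0.603. The similar slope in other cell types is consistent with a GC-dependent yield of the libraries, and the gap in slope between control 3 and the other controls was 66.8% of the gap between the group means. A response shared by all islet cells stays open, and no label gives a library batch that would separate it from the genotype.

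The fall of cell cycle genes kept a GC-corrected median of -0.67, which argues against the GC trend as its cause. Markers of endothelial, stellate, immune and nerve cells had a GC-corrected median of -0.0109 ± 0.0524, which argues against a lower share of these cells as a pool. That error too is across genes, which are not independent. A loss of a single class stays open, and lymphocytes had 1 measured marker. A single library would not give it either: the highest adjusted p without one library was 3.41e-05 after GC correction. Which cell type held these transcripts was not tested.

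Rab39 and Slc35f2 rose together on chromosome 9. GC content is not the cause, with the lower of the 2 corrected changes at 2.77, nor is a shift of the whole segment, since the 16 other tested genes within 1 Mb had a GC-corrected median of -0.12 and 0 of them rose. The genes lie on opposite strands, with the starts facing each other across 65.3 kb. Transcription running past the end of either gene therefore leads away from the other. The kit does not mark strand and no reads between the genes were examined, so antisense transcription across both was not tested. What raised the pair was not tested further.

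With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split, the 1 with the most calls in each case, called 3046 genes, and the highest of the others called 3. After GC correction these numbers were 1900 and 3, and for gene lists 5 and 3. Each of the other splits mixed control and knockout libraries on both sides. Any difference between the groups, from genotype or from a batch, then enters the spread and lowers the calls. The contrast therefore does not separate genotype from a batch that follows the groups.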
